A study of Homo sapiens with 2 samples.

How the data were processed

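Huh7 cells were seeded at 500000 per well and kept for 6 days in high glucose (4.5 g/L) or low glucose (0.45 g/L) medium, with subculture of live cells at high confluency, per the labels' protocols. RNA was extracted with a column kit and sequenced on libraries made with a standard Illumina protocol, 1 library per medium. How ribosomal RNA was avoided and whether the libraries keep strand are not given in the sources used here.

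The deposited values are TPM per gene, named as such per the file headers, with 2 decimals, a gene symbol and an interval per entry; each library sums to 1000000. The submitters' processing notes name cutadapt (an adapter trimmer), RSEM 1.2.21 (an estimator of transcript abundance that divides reads mapping to several genes between them) and the hg19 build. The aligner, the annotation and filters are not given in the sources used here. TPM corrects for transcript length and fixes the total, so a gene that takes a larger share lowers the values of all others. The number of reads behind a value is not given. Values of short entries of low level may fall in steps of few reads, but reads were not estimated from them. The depth was therefore not determined, and no counting interval is given. Coordinates are those of the authors' hg19 intervals, 1-based, and a value covers all transcripts of a gene.

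The design had planned scaled read counts with counting intervals. Because the values are TPM, the rule written for that case was used. Genes with a mean TPM of at least 1 over both libraries were compared by the difference of log2(TPM + 1), low minus high glucose, and a gene met the 2-fold rule at a difference of at least 1 or at most -1. With 1 library per medium no test between media is possible, and no p-value is given. The groups came from the treatment label of each sample, and no batch is named there.

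Before the data were examined, 38 gene lists were fixed, along with the rule for naming genes and the alternatives. For each list with at least 5 genes at the level compared (35 lists), the median difference was placed among 10000 random lists of the same size, matched member by member on mean expression in 20 groups. A list stood apart when its percentile was below 2.5 or above 97.5. This percentile describes these libraries and does not measure variation between cultures. Named genes were the 12 largest differences each way among genes past the 2-fold rule with at least 10 TPM in the library where they were higher. That level replaced a planned minimum of 200 reads once the values proved to be TPM. Up to 4 members past the rule were added for each list that stood apart, filled up to 2 with its most abundant members. For other lists the 2 most abundant members and up to 2 past the rule were added. A set chosen in advance (such as TXNIP, HSPA5, ASNS, ALB and MKI67) and the 5 most abundant genes of each library completed the 143 names, 4 of which are not reported here.

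The procedure was tested on simulated data for the comparison of low against high glucose, with 13513 genes compared and noise of SD 0.25 on the log2 scale. It recovered 96 of 100 genes seeded at 3-fold and 100 of 100 at 6-fold, and called 0 of 13313 unchanged genes. No gene of the lowest levels compared was seeded, so recovery there, where the log2(TPM + 1) scale shrinks differences, was not measured. The noise was assumed and is below the SD of the observed differences (0.50), so these counts check the procedure and give no rate of false calls among the genes past the rule. Of 1000 random lists of 20 genes, 6.6% stood apart, and 100 of 100 lists shifted by 0.5 did.

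Alternatives were median-of-ratios scaling, upper-quartile scaling, the total without the 50 most abundant genes, pseudocounts of 0.1 and 5, no filter on level, a mean of at least 10 TPM, and thresholds of 1.5-fold and 3-fold. The filters stand in for planned filters on reads. Chosen after the data were seen were trimmed-mean scaling (30% trimmed by difference and 5% by level at each end), rescaling without the MTRNR2L genes, subtraction of the median of each expression group, and a comparison limited to genes whose interval no other entry shares. The scalings moved the median difference of all genes to between -0.0032 and 0.084.

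Across the 13745 genes compared, log2(TPM + 1) of the libraries correlated with Pearson r = 0.969 and Spearman rho = 0.969; genes are not independent replicates. Entries at 0 in both libraries numbered 6552 (25.9%). The 50 most abundant genes held 19.1% of TPM in high and 20.8% in low glucose. In 28 entries a gene symbol had been turned into a date by spreadsheet software; 19 of them were at the level compared and counted, but none was named. Among the genes compared, 38 shared their interval with another entry, and 8 of these met the rule. Transcript length and GC content for the closing checks came from GENCODE release 29, matched by symbol for 92.8% of the genes compared, with no coordinates taken from it. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.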

Results

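RNA was sequenced from Huh7 cells, an established line derived from a well differentiated human hepatocellular carcinoma, after 6 days in medium with 4.5 g/L glucose (high glucose) or 0.45 g/L glucose (low glucose). Each medium is represented by 1 library. The values are TPM, a measure of transcript abundance that corrects for transcript length and sums to 1000000 in each library. The number of reads is not given and was not estimated here, so the depth was not determined. Of 25343 gene entries, 17994 were above 0 in the high glucose library and 18036 in the low glucose library, and 13745 had a mean of at least 1 TPM and entered the comparison.

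The comparison asks how the transcriptome of these liver cancer cells differs between abundant and scarce glucose. In low glucose, targets of ATF4, the transcription factor of the integrated stress response, were higher, as were chaperones of the endoplasmic reticulum. TXNIP, a glucose-induced inhibitor of glucose uptake and thioredoxin, was far lower. Genes of cholesterol synthesis, DNA replication, mitosis and histones were lower. Albumin and the other members of a fixed list of 28 secreted hepatocyte proteins were within 2-fold.

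In total, 502 genes (3.65% of those compared) were at least 2-fold higher in low glucose and 151 (1.10%) at least 2-fold lower, on the log2(TPM + 1) scale used for every difference given here. This scale understates the differences of genes of low level. The 25th and 75th percentiles of the difference, low minus high glucose, were -0.23 and 0.35, with a median of 0.05. Abundant genes tended lower, with a median of 0.20 in a group of genes near 2.0 TPM and -0.16 in a group near 158 TPM. Of 35 gene lists fixed beforehand and large enough to test, 19 stood apart from random lists of matched expression, 10 of them higher and 9 lower. A nominal 5% of these lists is 1.75, a figure that does not allow for genes regulated together or shared between lists. These differences have no replicate check and describe 2 libraries. With a pseudocount of 5, which discounts low genes, 234 and 79 genes met the 2-fold rule.

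**Figure D1:**
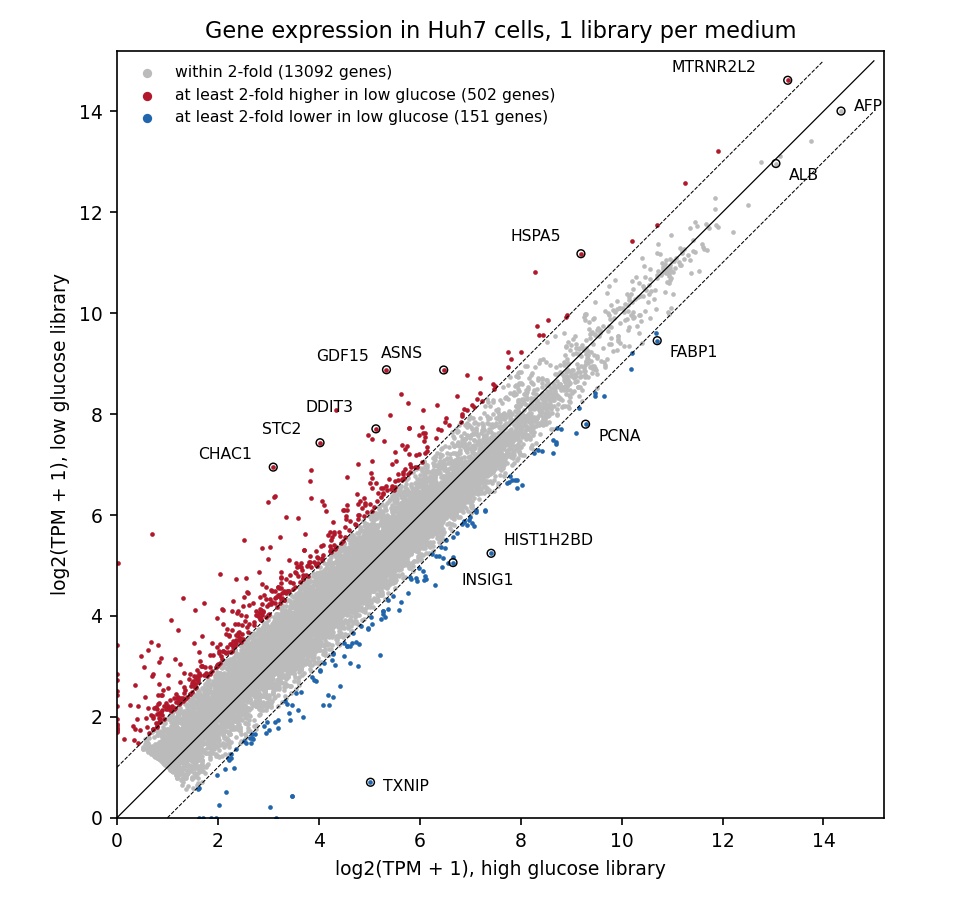
Expression of the 13745 genes compared, as log2(TPM + 1) in the high glucose library (x axis) and in the low glucose library (y axis), each point a gene, with the solid line at equal level and dashed lines at 2-fold. The 502 genes in red were at least 2-fold higher in low glucose and the 151 in blue at least 2-fold lower, with TXNIP far below the diagonal and CHAC1, STC2 and GDF15 above it.

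The list of ATF4 targets showed the largest median difference of the tested lists fixed beforehand. Of its 31 members, 18 were at least 2-fold higher in low glucose, none was 2-fold lower, and 29 lay above 0. The median log2 difference was 1.84, above all 10000 matched random lists, whose central 95% ran from -0.27 to 0.09. CHAC1 (chromosome 15, 41245636 to 41248717), which encodes a glutathione-degrading enzyme, stood at 7.56 TPM in high and 123 TPM in low glucose. The secreted glycoprotein gene STC2 (chromosome 5, 172741726 to 172756506) stood at 15.3 and 172 TPM. ATF3 (chromosome 1, 212738676 to 212794119), a stress-induced transcription factor, stood at 7.79 and 82.7 TPM. SLC7A11 (chromosome 4, 139085248 to 139163503), the cystine importer, stood at 13.4 and 118 TPM. Among the genes chosen in advance, DDIT3 (CHOP, a pro-apoptotic transcription factor) stood at 34.1 and 208 TPM. The pseudokinase gene TRIB3 stood at 48.5 and 335 TPM, and ASNS, which encodes asparagine synthetase, at 88.0 and 468 TPM. The summed TPM of the list was 3436 in high and 8849.95 in low glucose.

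Chaperones and other genes of the unfolded protein response of the endoplasmic reticulum were higher as a group. Of 24 members, 10 were at least 2-fold higher, none was 2-fold lower and 23 lay above 0, with a median of 0.88 at the 100th percentile of random lists. HSPA5 (BiP, the main chaperone of this compartment; chromosome 9, 127997127 to 128003666) stood at 585 TPM in high and 2316 TPM in low glucose. HERPUD1, a component of the degradation machinery of the endoplasmic reticulum, stood at 66.2 and 269.8 TPM. HYOU1 stood at 146 and 421 TPM, and DNAJB9 at 59.7 and 145 TPM; both encode chaperones. Heat shock proteins, a list dominated by cytosolic chaperones, did not stand apart (median -0.13, 49.3rd percentile). Of 14 members, 2 met the rule, both higher, while 6 lay above 0 and 8 below. The inducible HSPA6 is not on this list and stood at 0.63 and 48.0 TPM. HSPA1A stood at 66.3 and 196 TPM and HSPA1B at 31.7 and 113 TPM; these near-identical paralogs share reads, so their separate levels are uncertain, while their sum stood at 98.0 and 309 TPM. The abundant HSPA8 (1303 and 1001 TPM) and HSP90AA1 (1608 and 1240 TPM) remained within 2-fold.

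Genes of glucose sensing and use did not differ as a single group. TXNIP (chromosome 1, 145438438 to 145442628) stood at 31.6 TPM in high and 0.63 TPM in low glucose, a log2 difference of -4.32. It was the only one of 9 measured genes on the MondoA and ChREBP target list to meet the rule. The list did not stand apart (median 0.03, 33.7th percentile), with 5 members above 0 and 4 below. Named after their values were seen, PKLR (15.5 and 7.46 TPM, log2 difference -0.96) and KHK (-0.82) were lower but short of the rule. The list also holds the genes of the factors themselves, MLXIP (MondoA, 0.20) and MLXIPL (ChREBP, 0.55), which are not a measure of target response. KLF10 (22.5 and 36.3 TPM) and DAK (33.3 and 34.0 TPM) were within 2-fold, and ARRDC4, a relative of TXNIP, was listed at 0.02 and 0 TPM, below the level compared. Of 20 glycolysis genes, 5 were at least 2-fold higher and none 2-fold lower, with a median of -0.22 (5.82nd percentile). The higher members included SLC2A1 (GLUT1, a glucose transporter; 31.4 and 99.04 TPM) and HK2 (hexokinase 2, a glucose kinase; 26.6 and 59.9 TPM). LDHB (0.47 and 4.23 TPM) and ENO2 (0.78 and 5.27 TPM) also met the rule from low levels, and both missed it with a pseudocount of 5 (0.75 and 0.83). The abundant enzymes GAPDH (4755 and 3139.8 TPM), LDHA (818 and 504 TPM) and ENO1 (1078 and 933 TPM) were within 2-fold.

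Gluconeogenesis and hepatic glucose handling did not stand apart (median 0.12, 72.6th percentile), with 2 of 10 members higher. These were PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (65.0 and 215 TPM), and GCKR, the regulator of glucokinase (8.46 and 26.2 TPM). PC (212 and 190 TPM) and PYGL (178 and 125 TPM) were within 2-fold. The cytosolic carboxykinase PCK1 (0.22 and 0.08 TPM) and glucose-6-phosphatase G6PC (0.15 and 0.25 TPM) lay below the level compared in both media. Pentose phosphate genes (9 members, median -0.21, 18.1st percentile) and genes of hexosamine and glycosylation precursor synthesis (14 members, median -0.14, 21.9th percentile) held no member past 2-fold. PGD (329.5 and 285 TPM), TKT (305 and 281 TPM), UGP2 (192 and 173 TPM) and UGDH (130.4 and 151 TPM) were their most abundant members.

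Cholesterol synthesis and SREBP2 targets were lower in low glucose. Of 25 members, 8 were at least 2-fold lower, none was higher by that rule and 23 lay below 0, with a median of -0.64 that was below every random list. INSIG1, which holds back SREBP processing and is itself an SREBP target, stood at 100.1 TPM in high and 32.3 TPM in low glucose. The pathway enzymes IDI1 (258 and 95.1 TPM), MVK (68.7 and 25.5 TPM) and HMGCS1 (415 and 169.9 TPM) also met the rule. Fatty acid and triglyceride synthesis had a median of -0.26 over 18 members (3.02nd percentile), with none past 2-fold; subtracting the median of each expression level group moved it to the 2.0th percentile (median -0.22). FASN, the fatty acid synthase, stood at 253 and 147 TPM, SCD at 841 and 548 TPM and FADS2 at 698 and 575 TPM.

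Genes of mitochondrial fuel use were lower by small amounts. Fatty acid oxidation, ketogenesis and PPARA targets had a median of -0.30 over 25 members (0.3rd percentile), and 1 met the rule: FABP1, the liver fatty acid binding protein, at 1669.7 and 701 TPM. CPT1A, which carries fatty acids into mitochondria, stood at 3.97 and 7.93 TPM (0.85), and the lipid droplet gene PLIN2 stood at 317 and 338 TPM. The TCA cycle and pyruvate dehydrogenase list had a median of -0.29 with 22 of 23 members below 0 (2.25th percentile, median of random lists -0.10). It no longer stood apart with a pseudocount of 5 (2.67th percentile) or among genes of at least 10 TPM (2.51st percentile). IDH2 (263 and 249.6 TPM) and MDH2 (190.1 and 162 TPM) were its most abundant members. Nuclear-encoded oxidative phosphorylation genes had a median of -0.26 over 69 members (1.47th percentile, median of random lists -0.13), 59 of them below 0. The 2 most abundant by mean TPM went the other way, with COX6A1 at 834 and 1347 TPM and COX4I1 at 853 and 1026 TPM. The next, ATP5E (970 and 720 TPM) and ATP5B (999 and 680 TPM), named after their values were seen, were lower. A fixed list of 13 mitochondrially encoded mRNAs could not be compared, because 0 of them, and 0 entries on the mitochondrial chromosome, were among the values.

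Proliferation genes were lower. All 24 S phase genes lay below 0, 5 of them at least 2-fold lower, with a median of -0.69 below every random list. PCNA, the sliding clamp of DNA polymerases, stood at 624 TPM in high and 222 TPM in low glucose. UHRF1, which maintains DNA methylation, stood at 82.2 and 35.5 TPM, the flap endonuclease gene FEN1 at 227 and 102 TPM and the helicase subunit gene MCM6 at 126 and 59.2 TPM. With the median of each expression level group subtracted, FEN1 (-0.98) and MCM6 (-0.95) fell short of 2-fold. All 24 mitosis genes also lay below 0 (median -0.55), none by 2-fold, among them UBE2C (453 and 311 TPM), TPX2 (301 and 191 TPM) and MKI67, the proliferation marker (123 and 82.1 TPM). Of 12 replication-dependent histone genes, 7 were at least 2-fold lower, with a median of -1.16. Over all 56 core and linker histone genes measured, a family chosen after the differences were seen, the median was -0.43. Of these genes, 36 lay below 0 and 20 above, the latter including HIST1H2BH (18.2 and 28.6 TPM) and HIST1H4E (2.88 and 5.32 TPM). Whether lower histone values go with less DNA replication was not tested. HIST1H2BD (chromosome 6, 26158349 to 26171576) stood at 169.6 and 36.8 TPM, HIST1H2BC at 15.9 and 3.68 TPM, HIST1H2BJ at 23.7 and 7.34 TPM and the linker histone gene HIST1H1C at 396 and 149 TPM.

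The cell cycle inhibitor genes CDKN1C (p57; 20.3 and 5.11 TPM) and CDKN2C (p18; 26.5 and 7.10 TPM) were among the 12 genes with the largest negative differences. CDKN1A (p21) stood at 9.94 and 9.0 TPM, and CDKN2B (p15), named after its values were seen, was at least 2-fold higher at 18.9 and 41.7 TPM. The p53 and growth arrest list did not stand apart (median 0.20, 91.9th percentile), although 7 of 17 members were at least 2-fold higher. Among genes of at least 10 TPM the list's median was 1.10, above every random list. That filter left out CDKN1A, SESN1, ZMAT3 and FDXR, which all lay below 0 (-0.13, -0.66, -0.20 and -0.46). SESN1, ZMAT3 and FDXR were named after their values were seen. GDF15, a secreted stress cytokine, stood at 39.6 and 469.9 TPM. GADD45A, a growth arrest gene, stood at 44.5 and 151 TPM, and BBC3 (PUMA, a pro-apoptotic BH3-only protein) at 6.36 and 23.8 TPM. GDF15 and GADD45A are also known to respond to ATF4. BAX was within 2-fold (159.7 and 135 TPM).

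**Figure D2:**
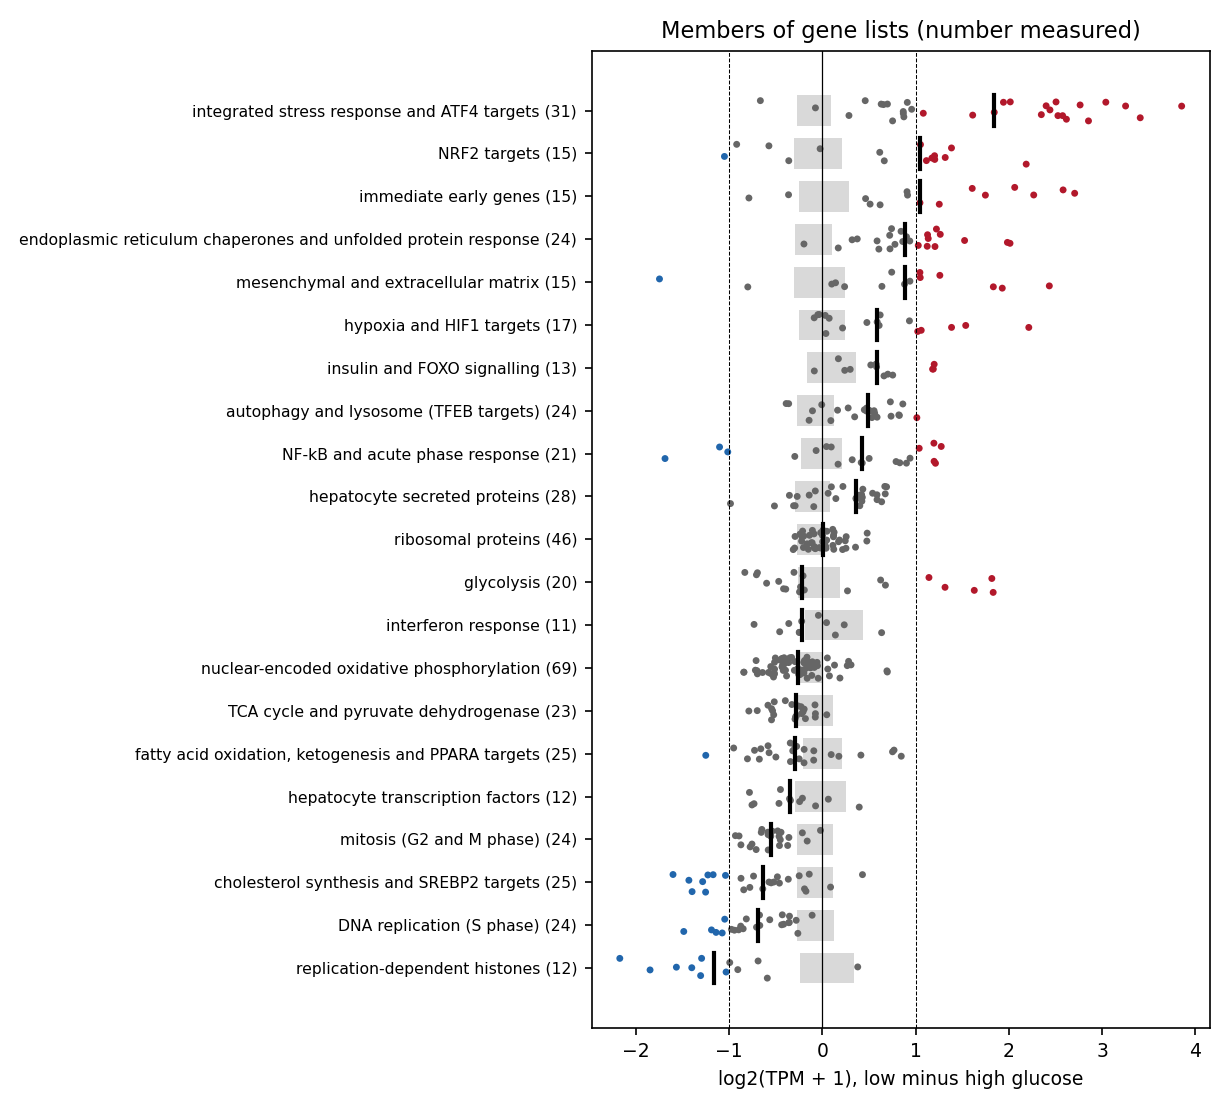
Members of the gene lists that stood apart, and of the glycolysis and ribosomal protein lists, each point a gene, by the difference of log2(TPM + 1) between the low and the high glucose library (x axis), with the number of genes measured in parentheses. The vertical bar marks the list median, the grey box the central 95% of 10000 random lists of matched expression, red and blue points genes at least 2-fold higher or lower; the ATF4 list has the highest median (1.84) and the histone list the lowest (-1.16).

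Several other stress-linked lists were higher. NRF2 targets of the antioxidant response had 8 of 15 members at least 2-fold higher, 1 lower and a median of 1.05, above every random list. Of these members, 10 lay above 0 and 5 below. The 1 at least 2-fold lower was AKR1C1 (707 and 341 TPM), named after its values were seen. NQO1 (107 and 71.2 TPM) and AKR1C3 (5.79 and 2.59 TPM), named in the same way, also lay below 0. OSGIN1 stood at 38.1 and 177 TPM, the sulfiredoxin gene SRXN1 at 66.5 and 175 TPM, AKR1B10 at 16.0 and 41.3 TPM and the heme oxygenase gene HMOX1 at 94.1 and 218 TPM. The most abundant members, the ferritin genes FTL (13904 and 10827 TPM) and FTH1 (8986 and 8835 TPM), stayed within 2-fold, and the list's summed TPM was lower in low glucose by a ratio of 0.881. Hypoxia and HIF1 targets had a median of 0.59 over 17 members (99.99th percentile), 5 of them at least 2-fold higher. These included the angiogenic factor VEGFA (67.4 and 197 TPM), the circadian repressor BHLHE40 (15.7 and 76.6 TPM), PDK1, which inhibits pyruvate dehydrogenase (8.10 and 22.8 TPM), and the collagen hydroxylase gene P4HA2 (48.9 and 103 TPM). On this hypoxia list 14 members lay above 0 and 3 below. NDRG1 (158 and 149 TPM), BNIP3 (188 and 197 TPM) and LOX (61.7 and 63.4 TPM), named after their values were seen, were nearly level. Autophagy and lysosome genes had a median of 0.49 over 24 members, above every random list, with 19 above 0. HEXA (64.7 and 131 TPM) alone met the rule, and it fell short of 2-fold under 3 alternatives (0.95 to 0.97); the protease gene CTSD stood at 278 and 493 TPM.

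Matrix and early response genes were higher as well. Mesenchymal and extracellular matrix genes had 6 of 15 members at least 2-fold higher and 1 lower (median 0.88, above every random list). THBS1 stood at 32.5 and 179.6 TPM and CYR61 at 54.3 and 209 TPM, while S100A4, a calcium-binding protein, stood at 17.2 and 4.41 TPM. Immediate early genes had 8 of 15 members higher (median 1.05, above every random list). FOS stood at 1.92 and 16.5 TPM, FOSB at 0.54 and 9.04 TPM, FOSL1 at 0.78 and 7.56 TPM and KLF4 at 3.22 and 16.6 TPM. NF-kB and acute phase genes split: 5 of 21 members were higher and 3 lower, with a median of 0.43 (99.96th percentile). The adhesion molecule ICAM1 stood at 146 and 341 TPM, CXCL2 at 8.89 and 21.7 TPM and SOCS3 at 1.51 and 5.07 TPM, while the serum amyloid gene SAA4 stood at 78.0 and 23.5 TPM. CXCL2 (0.94) and SOCS3 (0.63) missed the rule with a pseudocount of 5. Insulin and FOXO signalling genes had a median of 0.58 over 13 members (99.9th percentile), with 3 past 2-fold. IRS2 (3.92 and 10.3 TPM) and IGFBP1 (1.32 and 4.29 TPM) met the rule from low levels and missed it with a pseudocount of 5 (0.78 and 0.56); IGFBP2 stood at 14.7 and 34.7 TPM. Interferon response genes had a median of -0.22 over 11 members (1.55th percentile), none past 2-fold, and the call was lost under 4 alternatives. ISG15 stood at 41.4 and 42.7 TPM.

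Lists of liver identity genes had small median differences. Secreted hepatocyte proteins had a median of 0.36 over 28 members, above every random list, with 19 above 0 and none past 2-fold. Albumin (ALB) stood at 8528 and 7997 TPM, apolipoprotein A1 (APOA1) at 3151 and 2542 TPM and AMBP at 3673 and 4960.0 TPM. Hepatocyte transcription factors had a median of -0.35 over 12 members (0.65th percentile), with CEBPA at 333 and 193 TPM and HNF4A at 211 and 154 TPM. Fetal liver and hepatoma markers did not stand apart (median 0.07, 85.3rd percentile). The fetal albumin homologue AFP stood at 20859 and 16441 TPM and IGF2 at 1801 and 1922 TPM, while the secreted phosphoprotein SPP1 (52.5 and 165 TPM) and the progenitor marker PROM1 (54.0 and 146 TPM) met the rule. Urea cycle and amino acid breakdown genes had 3 of 18 members higher and 3 lower (median 0.04, 51.7th percentile). The lower ones included the glutamate dehydrogenase gene GLUD1 (447 and 207 TPM), which missed the rule with the median of each expression level group subtracted (-0.97). OTC (9.80 and 2.85 TPM) and TDO2 (6.80 and 2.20 TPM) missed it with a pseudocount of 5 (-0.91 and -0.71).

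The remaining lists did not stand apart. Cytochrome P450 and conjugation enzymes had a median of 0.22 over 15 members (82.9th percentile), with POR at 160.3 and 247 TPM and SULT2A1 at 101 and 67.5 TPM. Bile acid synthesis and transport had a median of 0.23 over 9 members (88.4th percentile), with FGFR4 at 415 and 486 TPM, KLB at 147 and 112 TPM and the transporter gene SLC51A at 4.28 and 13.2 TPM (0.97 with a pseudocount of 5). Epithelial junction genes had a median of 0.10 over 11 members (80.3rd percentile); the keratins KRT8 (3299 and 2438 TPM) and KRT18 (1891 and 1765 TPM) have overlapping loci and may share reads. Glutamine, serine and one-carbon genes had a median of 0.04 over 15 members (73.7th percentile), with AHCY at 484 and 373 TPM, SLC38A2 at 294 and 435 TPM and the amino acid transporter SLC38A1 at 78.7 and 183 TPM. The 46 ribosomal protein genes had a median of 0.00 (96.4th percentile) and a summed TPM of 80239 and 80068; RPS2 stood at 3742 and 3446 TPM and RPS12 at 3379 and 3302 TPM.

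Markers of other cell types gave few measured genes. Fibroblast and stellate cell markers had a median of 0.34 over 5 members (82.0th percentile). COL1A2 stood at 18.7 and 24.6 TPM, PDGFRA at 13.8 and 7.89 TPM and COL1A1 at 1.06 and 4.03 TPM (0.58 with a pseudocount of 5). PECAM1 (1.35 and 1.25 TPM) was the only endothelial marker at the level compared. Of 4 leukocyte markers at that level, LYZ, the lysozyme gene, stood at 550.3 and 198 TPM and CD68 at 20.4 and 39.3 TPM.

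Of the 12 genes with the largest positive differences, several belonged to no list. HSPA6, an inducible heat shock protein (chromosome 1, 161494036 to 161496687), stood at 0.63 and 48.0 TPM. INHBE, the inhibin beta E chain (chromosome 12, 57849096 to 57851791), stood at 19.3 and 271 TPM, and SH3BP2, a signalling adaptor, at 6.98 and 75.9 TPM. AREG, an EGF receptor ligand, stood at 7.67 and 81.4 TPM; its locus spans a pair of near-identical copies, so its level is uncertain. CYP26A1, which breaks down retinoic acid, stood at 1.47 and 19.4 TPM and AKNA, a DNA-binding and centrosomal protein, at 4.71 and 44.6 TPM. Among the 12 largest negative differences were the homeobox gene HOXD1 (36.1 and 8.39 TPM), the pepsinogen C gene PGC (18.5 and 4.27 TPM) and LOC101929633 (17.5 and 3.69 TPM). LOC102723859 (0.01 and 32.3 TPM) had the largest positive difference, and LOC101060389 and LOC102724862 (each 10.1 and 0.35 TPM) followed TXNIP among the negative ones. These 3 entries cover nearly the same interval of chromosome 17 (36284017 to 36348609), so the division of reads between them is uncertain, and their sum stood at 20.3 and 33.0 TPM.

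The 5 most abundant genes of high glucose were AFP, FTL, MTRNR2L2, FTH1 and ALB. MTRNR2L2 and MTRNR2L8, nuclear genes that resemble the mitochondrial 16S ribosomal RNA, joined AFP, FTL and FTH1 in low glucose. MTRNR2L2 stood at 10029.9 and 25094 TPM and MTRNR2L8 at 3855 and 9542 TPM. The MTRNR2L genes held 1.71% of all TPM in high and 4.28% in low glucose, and since near-identical copies share reads, their separate levels are uncertain. With 0 entries on the mitochondrial chromosome, reads of its ribosomal RNA cannot be told apart from reads of these copies.

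**Figure D3:**
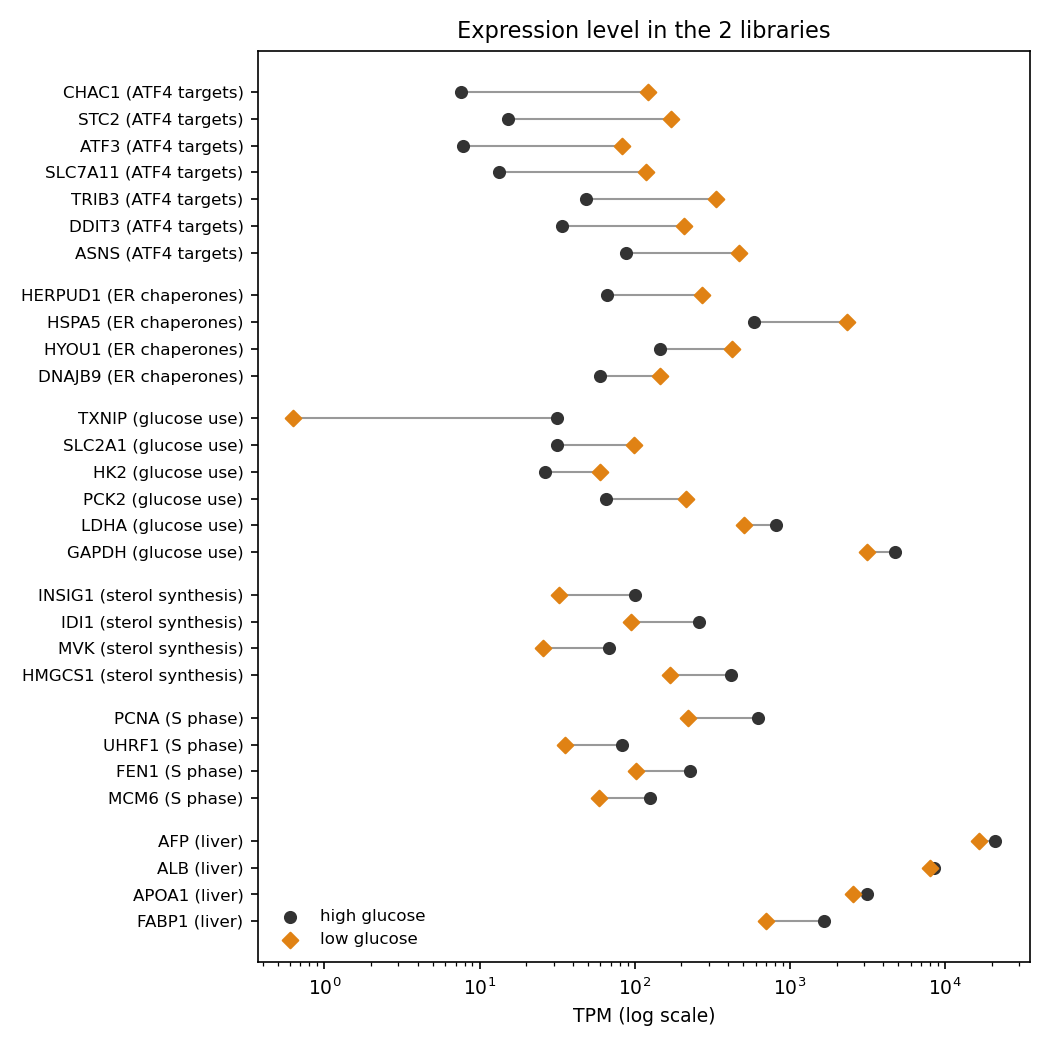
TPM on a log scale (x axis) of named genes, 1 row per gene, in the high glucose library (dark circles) and the low glucose library (orange diamonds), joined by a line. TXNIP shows the widest gap toward low glucose being lower (31.6 and 0.63 TPM), CHAC1 is the first of the higher ATF4 targets (7.56 and 123 TPM), and ALB lies at almost the same level in both (8528 and 7997 TPM).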

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

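Trimmed-mean scaling, rescaling without the MTRNR2L genes, subtraction of the median of each expression group and the limit to genes with an interval of their own were chosen after the data were seen; the other alternatives were planned. The number of genes at least 2-fold higher was 502 and lower 151. It became 234 and 79 with a pseudocount of 5, 1786 and 835 at 1.5-fold, 119 and 22 at 3-fold, and 293 higher among genes of at least 10 TPM, which compares fewer genes; 19 other counts stayed within 1.5 times. The share of higher genes among those past the rule was 76.9% and lay between 70.4% and 81.2% under the scalings. Of the list medians, 341 values kept their call. Interferon response lost its call with the expression group median subtracted (-0.23), a pseudocount of 5 (-0.12) and no filter (-0.014), and reversed to 0.044 at 10 TPM. The TCA cycle list lost its call with a pseudocount of 5 (-0.27) and at 10 TPM (-0.29). Fatty acid and triglyceride synthesis gained one with the expression group median subtracted (-0.22), as did p53 targets at 10 TPM (1.10). Apart from the changed sets of genes, the cause was not tested. Of values of named genes, 1100 kept their side of 2-fold, 17 fell short of it, 3 crossed it and none reversed. Scaling by total count and a counting interval beyond 2-fold were not run, because the values are TPM. No paired analysis was possible because each medium has 1 library, and leaving out a library was not possible for the same reason. Depth was not estimated, so counting error in low genes such as IGFBP1 was not measured.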

Other observations

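The gene families in the first 3 paragraphs, and the genes named in them, were chosen after the differences had been seen, as were the tests of chance, of both MTRNR2L explanations, of the small RNAs with a pseudocount of 5, and of glycolysis, with its split at 100 TPM; the length and GC tests of the ATF4 and chaperone lists were chosen before. Amino acid transporters were higher in low glucose. Of 29 measured, 9 were at least 2-fold higher and 2 lower, with a median of 0.71, and their summed TPM was 1652 in high and 4720.4 in low glucose. SLC3A2, the heavy chain of several exchangers, stood at 311 and 1795 TPM, the cationic transporter SLC7A1 at 13.2 and 101 TPM and the neutral transporter SLC1A4 at 16.1 and 72.3 TPM. The ATF4 list holds 5 of these genes. The other 24 had a median of 0.56, above every matched random list. Cytosolic tRNA synthetases had a median of 0.32 over 20 genes (99.97th percentile), led by CARS (39.4 and 94.2 TPM). Without the 4 that the ATF4 list holds, the median was 0.11 (96.5th percentile). Mitochondrial tRNA synthetases had a median of -0.12 over 17 genes (6.75th percentile).

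Collagens and laminins were higher, with 25 of 26 genes above 0, 6 at least 2-fold higher, 1 lower and a median of 0.57 above every random list. COL12A1 stood at 4.29 and 16.0 TPM, COL18A1 at 112 and 229 TPM and the laminin chain LAMB1, also in the extracellular matrix list, at 222 and 425 TPM. COL14A1 went the other way, from 40.6 in high to 16.6 TPM in low glucose. Proteasome subunits and mitochondrial ribosomal proteins were lower by small amounts. Of 37 proteasome subunits, 35 lay below 0 (median -0.33, median of random lists -0.11, 0.2nd percentile). The same held for 69 of 77 mitochondrial ribosomal proteins (median -0.27, median of random lists -0.09, 0.04th percentile). None of either group met the 2-fold rule.

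The 13 tubulins as a group did not stand apart (median -0.26, 3.26th percentile), with TUBA1B at 2009.8 and 1102 TPM, TUBB at 1132 and 653 TPM and TUBB4B at 1180.4 and 589 TPM. The 8 CCT chaperonin subunits did not stand apart either (median -0.36, 8.24th percentile). In the wider family of 56 core and linker histone genes, 14 were at least 2-fold lower, 1 was higher and 20 lay above 0, with a median of -0.43 below every random list. The higher one was HIST3H2A (26.6 and 62.6 TPM).

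The higher ATF4 targets and endoplasmic reticulum chaperones were weighed first. A trend with transcript length, GC content or expression level was argued against, mainly by its small size. Median differences were 0.06 and 0.12 in the groups of shortest and longest transcripts. They were 0.02 and 0.09 in the groups of lowest and highest GC content. Removing trends this small could move the list medians little, so the removal adds little. With them removed, the ATF4 list kept a median of 1.90 over 31 genes, where random lists ran from -0.16 to 0.19. The chaperone list kept 0.98 over the 23 of 24 genes with a value. What stays open is a difference between the single cultures other than glucose, by chance or through subculture at high confluency. Such a difference cannot be told apart from an effect of glucose because each medium has 1 library. A response of the cells to scarce glucose is the biological hypothesis that the design names, and it was not tested against other cultures.

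The MTRNR2L genes, 7 of 7 at least 2-fold higher with TPM ratios between 2.48 and 2.70, had log2 differences with an SD of 0.043, where matched random sets ran from 0.179 to 0.965. This is consistent with reads of 1 source, possibly mitochondrial ribosomal RNA, being divided among near-identical copies, so that they count as 1 observation. More RNA without a poly(A) tail in the low glucose library cannot be told apart here. Small nucleolar and Cajal body RNAs were higher as a group (median 0.66 over 68, random lists 0.05 to 0.29). Several hold nearly the same values, such as SNORA15 (1.01 and 1.21 TPM), SNORA41 (1.02 and 1.22 TPM) and SNORA34 (0.97 and 1.16 TPM), as steps of few reads would give. The random lists were matched on TPM and not on reads, so this comparison decides nothing. Histone genes, whose transcripts mostly lack such a tail, were lower along with S phase genes (median -0.43 over 56, with 20 above 0). Whether the histone transcripts measured here lack a tail was not tested, so they do not decide it either. Most of the small RNAs lay at low levels (median 2.86 TPM), and with a pseudocount of 5 their median was 0.31 (random lists 0.02 to 0.14), with 7 at least 2-fold higher and 0 lower in place of 24 and 3. More mitochondrial RNA per cell stays open as a biological hypothesis and was not tested. The values hold 0 entries on the mitochondrial chromosome, so reads of its ribosomal RNA have no entry of their own.

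Glycolysis split by level. The 10 members of at least 100 TPM had a median of -0.43 (2.03rd percentile), and the 10 below that level a median of 0.91, above every random list, although PFKL, PFKM and ALDOC among them, named after their values were seen, lay below 0. The gap of 1.34 between these medians was above that of every random list of matched expression (central 95% from -0.27 to 0.60). Those lists carry any expression level trend, but the cut at 100 TPM was chosen after these differences were seen. The random lists had no such choice, so these ranks do not decide whether that trend is the whole cause. With length, GC content and expression trends removed, the abundant members had a median of -0.35 (0.35th percentile). No biological explanation of the split was tested.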
